A study of Mus musculus with 2 samples.

How the data were processed

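Total RNA-seq was measured in 2 biological replicate libraries of gastrocnemius from male B6CASTF1/J mice aged 14 days, with 300 ng of RNA per library. The labels mention 3 males, and whether a library held RNA of 1 animal or of a pool is not clear from them. They give the same donor identifier for both libraries, so whether the libraries came from different animals is not settled by the labels. RNA was extracted with a kit for animal tissue, and the added ERCC RNAs followed a profile for stranded libraries with reduced ribosomal RNA. The reference build was mm10 with the GENCODE M21 annotation, per the labels and the deposited description. Names of the aligner and the quantifiers are not given in the sources used here.

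The authors made a gene table and a transcript table for each library from reads aligned to the transcriptome, and a second transcript table directly from the reads and an index. The deposited tables give expected counts (estimated reads, not whole numbers, not normalised) per gene and per transcript. The deposited TPM values were scaled by the authors to a fixed sum over all entries of a table, added RNAs included. The other columns of the deposited gene table that were used are the lower and upper bounds of the quantifier's own interval of the TPM. The gene table held 55536 annotated genes, all of which matched the M21 annotation by identifier, 26248 entries with numeric identifiers (median length 73 bases, 3 and 1 counts in all) that were left out of gene analyses, and 97 entries for added control RNAs, 96 of them ERCC RNAs. The second transcript quantification was summed per gene where it is compared with the gene table. Floors and binomial tests cover counting error only, and the floor was set at 3 counts. Error estimates and p-values describe the spread between these 2 libraries and no wider population. The reference is not specific to the CAST alleles of these hybrids, and alleles were not separated.

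Expected counts were rounded for count models. Log ratios used log2(TPM + 1). Agreement between the libraries was computed over genes with a mean of at least 1 TPM. The dispersion was estimated with edgeR 4.0.16 (common dispersion, TMM scaling, genes kept by filterByExpr), run in R 4.3.3. Genes beyond sampling noise were found with a two-sided exact binomial test on rounded counts given TMM-scaled library sizes, for genes with at least 10 counts over both libraries, adjusted by Benjamini-Hochberg over all genes tested at 0.05. Pairs of genes were fixed before the data were examined, 14 of fast over slow forms and 26 of mature over developmental or ubiquitous forms. Their within-library log2 ratios were tested together with limma 3.58.1 (lmFit on an intercept, eBayes, two-sided, n = 2 libraries) and adjusted over the 40 pairs. In that fit all pairs took a common spread of 0.185 on the log2 scale, several pairs share a member, and an exact sign-flip test on 2 libraries cannot go below 0.5, so the p-values depend on the pooled spread. Ratios of TPM are means of the per-library ratios with their SD.

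The 37 gene lists and the 30 genes for transcript shares were also fixed before the data were examined. The lists are myosin heavy chains, fast fibre, slow fibre, embryonic and neonatal muscle, sarcomere scaffold, satellite cell and myogenic, cell division, replication-dependent histone, neuromuscular junction, glycolysis and glycogen, nuclear oxidative phosphorylation, mitochondrially encoded protein, fatty acid, cytosolic ribosomal protein, collagen and matrix, fibro-adipogenic progenitor, tendon, endothelial, pericyte and smooth muscle, macrophage, lymphocyte, neutrophil and mast cell, erythroid, Schwann cell, adipocyte, skin epithelium, cartilage and bone, immediate early, heat shock and stress, clock, atrophy and growth control, interferon response, dystrophin complex, excitation-contraction coupling, long noncoding RNA, imprinted and sex chromosome genes. Some genes stand in more than 1 list, and 4 symbols (Ahsp, Murf1, Redd1 and Zac1) were absent from the annotation. For Aldoa, Ddit3 and Rmrp, which have more than 1 identifier, the entry with the higher mean TPM was used. Each list's median log2 difference over members with a mean of at least 1 TPM was placed among 10000 random lists of the same size matched on expression in 20 bins, drawn with replacement. This percentile describes these 2 libraries and is not a p-value. The lymphocyte and the cartilage and bone lists had too few such members.

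Genes are named by a rule fixed before the data were examined: members of pairs, all listed myosins, the 4 members of each list with the highest mean TPM, the 15 protein-coding genes with the highest mean TPM, the 10 genes with the largest difference in each direction among those past the binomial test with at least 200 counts, and transcripts with a mean share of at least 10%. Some genes that meet this rule are not reported here. Genes outside this rule are marked as chosen after their values were seen, except those that belong to the tests of the closing section. Those tests used separate lists, of glucocorticoid and FOXO response genes and of adipocyte genes, written before their values were viewed. They also compared mitochondrial genes with nuclear copies by blastn 2.17.0, counting copies with at least 99% identity over at least 200 bases.

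Alternatives were tried for the pseudocount, the filters on TPM and counts, the scaling (TMM, DESeq2 1.42.0 size factors, added RNA totals), the quantification, the number of expression bins and the left-out library. The scaling of the list differences was added after the data had been seen. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and matplotlib 3.10.9 for plots. The tests were tried on simulated data: the binomial test called 0.0528% of 17060 unchanged genes, 62.3% of 53 genes changed by 0.5 on the log2 scale and 89.6% of 48 genes changed by 1. The pair model called 2% of 400 pairs with no difference and all of 400 pairs with a log2 ratio of 1 to 5. These pairs were simulated as independent, while some real pairs share a member. Of 200 random lists with no shift, 1.5% fell outside the 1st to 99th percentile. All of 100 lists of 14 genes shifted by 0.5 on the log2 scale did, a shift larger than most list medians found here. The differences in that trial of lists were simulated as independent between genes, which real lists need not be.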

Results

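Total RNA was sequenced from the gastrocnemius, the large fast-contracting calf muscle, of male B6CASTF1/J mice at an age of 14 days. These mice are the offspring of a cross between C57BL/6J and CAST/EiJ. The series held 1 group with 2 biological replicates, each library made from 300 ng of RNA with synthetic ERCC RNAs added. No treatment or second condition was given by the labels, so the comparisons made were between genes within a library, between the 2 libraries, and between 2 quantifications of each library. The quantified tables held 40825601 expected counts for replicate 1 and 37329025 for replicate 2. Added RNAs took 0.731% and 0.881% of these counts. A count of 3, taken as the floor, corresponded to 0.0740 CPM in replicate 1 and 0.0811 CPM in replicate 2. A transcript level of at least 1 TPM was reached by 12246 genes in replicate 1 and 12031 in replicate 2, of which 11136 and 11000 were protein-coding. Gene positions are on GRCm38 (mm10) with the GENCODE M21 annotation.

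The most abundant messenger RNAs encoded the contractile apparatus of fast muscle fibres and the enzymes that supply it with energy. Acta1, the skeletal muscle actin (ENSMUSG00000031972.5, chromosome 8, 123891769 to 123894751), stood first with 27605 ± 1435 TPM (SD, n = 2). Mylpf, the regulatory light chain of fast myosin (ENSMUSG00000030672.12, chromosome 7, 127208890 to 127214298), followed with 27199 ± 1686 TPM (SD, n = 2). Ckm, the muscle creatine kinase (ENSMUSG00000030399.2, chromosome 7, 19404776 to 19422841), had 16679 ± 1052 TPM (SD, n = 2), and Myl1, an essential light chain of fast myosin (ENSMUSG00000061816.15, chromosome 1, 66924295 to 66945404), had 14491 ± 550.4 TPM (SD, n = 2). Myh4, the heavy chain of the fastest fibre type IIb (ENSMUSG00000057003.12, chromosome 11, 67238029 to 67260446), had 12108 ± 148 TPM (SD, n = 2). The 15 highest protein-coding genes also held fast troponins and tropomyosin (Tpm1, Tnnt3, Tnnc2 and Tnni2), the calcium buffer parvalbumin (Pvalb, 9470 ± 1159 TPM; SD, n = 2), the calcium pump Atp2a1 (8140 ± 226 TPM; SD, n = 2), and the glycolytic enzyme Aldoa. The mitochondrial genome contributed mt-Co1 (11353 ± 662 TPM; SD, n = 2), mt-Cytb and mt-Nd1, which encode respiratory chain subunits. Their place among the mitochondrial genes depends on how reads were divided with near-identical nuclear copies. Taken with such copies, mt-Atp6 had 13708 ± 1060 TPM, mt-Co2 13060 ± 638 TPM and mt-Co3 10572 ± 553 TPM (SD, n = 2 for each). These sums lie above mt-Cytb (6370 TPM) and mt-Nd1 (5126 TPM), for which no such copy was found.

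By biotype, nuclear protein-coding genes took 46.9 ± 0.554% of all TPM (SD, n = 2) and mitochondrial genes 14.7 ± 1.10% (SD, n = 2), while mitochondrial ribosomal RNA took 9.94 ± 0.619% of counts (SD, n = 2). Reads given to near-identical nuclear copies of mitochondrial genes are not in the mitochondrial share. Genes of the class misc_RNA took 27.6 ± 0.758% of TPM but 4.45 ± 0.189% of counts (SD, n = 2 for both), since these genes are short. The class was led by Rn7s1 and Rn7s2, copies of the RNA of the signal recognition particle, whose listed values were identical within each library and which were chosen after their values were seen, and by Rn7sk, a regulator of transcription elongation, with 16520 ± 1663 TPM (SD, n = 2). The 10 highest genes together took 47.5 ± 0.357% of TPM (SD, n = 2). When the share was taken within nuclear protein-coding genes alone, the 10 highest of these took 30.9 ± 1.32% (SD, n = 2).

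The fast form of every contractile and calcium-handling pair was the more abundant one, which addresses the fibre type of the muscle at this age. Among thick and thin filament genes, fast troponin T Tnnt3 was 69.6 ± 4.94 times the slow form Tnnt1 in TPM, fast troponin I Tnni2 was 78.4 ± 9.33 times Tnni1, and the fast light chain Mylpf was 90.9 ± 7.89 times the slow Myl2 (SD, n = 2 for each). The calcium pump of fast fibres, Atp2a1, was 92.2 ± 12.9 times Atp2a2, the form of slow fibres and heart, and the calcium-storage protein Casq1 was 59.8 ± 14.1 times Casq2 (SD, n = 2 for both). Pairs with a smaller excess were myosin-binding protein C (Mybpc2 over Mybpc1, 3.99 ± 0.446), alpha-actinin (Actn3 over Actn2, 4.15 ± 0.584) and calsarcin (Myoz1 over Myoz2, 7.09 ± 0.287; SD, n = 2 for each). The fast myosins Myh2 and Myh1 were 3.13 ± 0.118 and 7.18 ± 0.474 times the slow Myh7 (SD, n = 2 for both), and the log2 ratio of Myh1 over Myh7 went from 2.84 to 4.14 in the second quantification. Actn2 and Mybpc1 are also made in fast fibres.

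Among the 9 sarcomeric myosin heavy chains, Myh4 took 79.6 ± 1.04% of the summed TPM (SD, n = 2). The fast IIx chain Myh1 (chromosome 11, 67200052 to 67224575) took 11.9 ± 0.403% and the fast IIa chain Myh2 (chromosome 11, 67171027 to 67197517) took 5.21 ± 0.324% (SD, n = 2 for both). The slow chain Myh7 (chromosome 14, 54970684 to 54994626) took 1.67 ± 0.166%, the neonatal chain Myh8 1.12 ± 0.110%, the cardiac chain Myh6 0.340 ± 0.0256% and the embryonic chain Myh3 0.0957 ± 0.00657% (SD, n = 2 for each). Myh13 and Myh7b, chains of extraocular and other specialised muscles, took 0.0145 ± 0.00120% and 0.00427 ± 0.00223% (SD, n = 2 for both). In the second quantification Myh1 took 19.1%, Myh7 1.08% and Myh6 0.138%, and Myh6 took 0.0811% as a share of counts. All 14 fast members were higher than their slow partners in both libraries, by limma on the within-library log2 ratios with a largest adjusted p of 2.0e-15 in this family. These p-values rest on a spread pooled over pairs that share members, and their size depends on the fit. In the second quantification the largest adjusted p of this family was 0.000499 (limma), for Actn3 over Actn2. An exact sign-flip test on 2 libraries alone cannot go below p = 0.5.

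Mature muscle forms were higher than their developmental or ubiquitous counterparts in all 26 pairs. Only pairs with a developmental partner bear on maturation, while a ubiquitous partner shows the muscle character of the tissue. With a single age in the series, the pairs cannot place the muscle on a course of maturation. The fast myosin Myh4 was 834 ± 68.1 times the embryonic Myh3 and 71.3 ± 7.94 times the neonatal Myh8, and skeletal actin Acta1 was 7.33 ± 0.436 times Actc1, the cardiac actin made in developing muscle (SD, n = 2 for each). Chrne, the adult subunit of the acetylcholine receptor at the nerve-muscle synapse, was 37.5 ± 16.6 times the fetal subunit Chrng, which stood at 0.540 ± 0.198 TPM (SD, n = 2 for both). Among energy enzymes, Ckm was 1843 ± 80.3 times the brain form Ckb, muscle glycogen phosphorylase Pygm was 498 ± 59.3 times Pygb, and muscle phosphofructokinase Pfkm was 177 ± 20.6 times Pfkl (SD, n = 2 for each). The muscle glucose transporter Slc2a4 was 41.3 ± 11.2 times Slc2a1, and Myf6, a regulator of differentiated fibres, was 44.5 ± 2.13 times Myf5, a regulator of muscle precursors (SD, n = 2 for both).

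The smallest ratios were those of Dmd, encoding dystrophin, over its homologue Utrn (2.97 ± 0.0173), the kinase subunits Prkag3 over Prkag1 (2.25 ± 0.618), and the cytochrome oxidase subunits Cox7a1 over Cox7a2 (1.69 ± 0.101; SD, n = 2 for each). The first member was over 2-fold higher in both libraries in 24 of the 26 pairs. Developmental genes of the same muscle were still abundant in absolute terms: Actc1 had 3780 ± 421 TPM, the imprinted RNA H19 had 4072 ± 314 TPM and the growth factor gene Igf2 had 1223 ± 75.6 TPM (SD, n = 2 for each). By limma, all 26 pairs passed with a largest adjusted p of 1.1e-06. In the second quantification Cox7a1 over Cox7a2 turned to -0.19 on the log2 scale and no longer passed (adjusted p = 0.123, limma), which left 25 of 26 pairs.

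**Figure D1:**
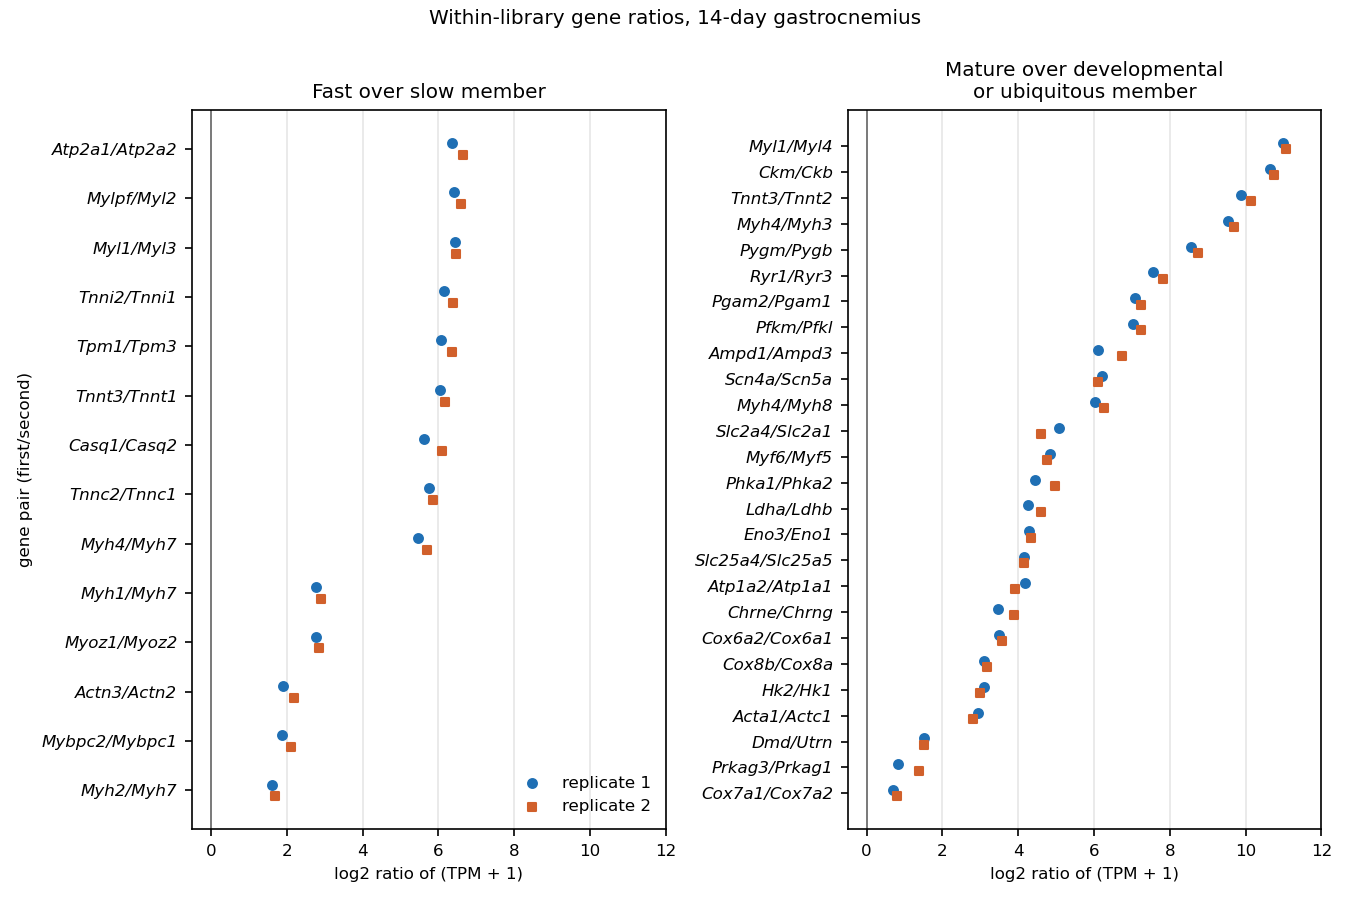
Each row is a gene pair, and the horizontal axis is the log2 ratio of (TPM + 1) of its first member over its second in each library, with circles for replicate 1 and squares for replicate 2. All 40 pairs lie to the right of 0 in both libraries.

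Gene groups fixed before the data were examined gave the make-up of the tissue. Of 486 memberships in 37 lists, 406 reached 1 TPM in both libraries. Muscle and energy groups were complete: 14 of 14 fast fibre genes (median 6866 TPM), 11 of 11 slow fibre genes (median 149 TPM), 18 of 18 sarcomere scaffold genes (median 371 TPM), 16 of 16 glycolysis and glycogen genes (median 959 TPM) and 18 of 18 nuclear oxidative phosphorylation genes (median 467 TPM). The giant filament proteins nebulin (Neb, 2119 ± 25.2 TPM) and titin (Ttn, 1822 ± 98.7 TPM) led the scaffold group, and Aldoa and Gapdh (4579 ± 66.1 TPM) led glycolysis (SD, n = 2 for each). The 15 fatty acid uptake and oxidation genes had a median of 142 TPM, the 13 mitochondrially encoded protein genes 3292 TPM and the 15 cytosolic ribosomal protein genes 244 TPM, and every one of these genes was detected. Of the 17 excitation-contraction coupling genes, 16 were detected (median 150 TPM), led by the luminal calcium-binding protein Srl and triadin (Trdn, 697 ± 7.79 TPM; SD, n = 2). All 14 dystrophin complex genes were detected (median 44.8 TPM), with dystroglycan (Dag1) at 99.3 ± 7.49 TPM (SD, n = 2).

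Connective tissue, vessel, nerve and blood cells were also represented. The collagen and matrix group was complete (18 of 18, median 94.3 TPM) with Col1a1, the main fibrillar collagen, at 1358 ± 339 TPM (SD, n = 2). Fibro-adipogenic progenitor markers (12 of 12, median 30.3 TPM) were led by the matrix proteoglycan gene Dcn, which the matrix list also holds. Tendon markers (10 of 10, median 10.9 TPM), endothelial markers (12 of 12, median 16.3 TPM) and pericyte and smooth muscle markers (9 of 10, median 15.8 TPM) were led by Fmod, Cdh5 and Acta2. Macrophage markers reached 1 TPM in 10 of 12 cases (median 5.5 TPM), led by the scavenger receptor Mrc1 (11.6 and 10.2 TPM). Schwann cell markers reached it in 10 of 12 (median 2.51 TPM), and erythroid markers in 7 of 10 (median 9.32 TPM), led by the globin Hbb-bs at 594 ± 124 TPM (SD, n = 2). No lymphocyte marker of 10 reached 1 TPM in both libraries. Only 5 of 10 neutrophil and mast cell markers, 4 of 10 adipocyte markers, 3 of 10 skin epithelium markers and 2 of 10 cartilage and bone markers did. The mast cell proteases Tpsb2 and Cma1 stood at 4.03 ± 0.304 and 3.18 ± 0.382 TPM (SD, n = 2 for both).

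Cell division, myogenic and early muscle genes were also detected. Of the 15 cell division genes 14 reached 1 TPM in both libraries, at a median of 2.83 TPM, with the proliferation marker Mki67 at 4.38 ± 0.884 TPM (SD, n = 2). All 10 replication-dependent histone genes were detected, at a median of 32 TPM. Satellite cell and myogenic differentiation genes were detected in 16 of 18 cases (median 12.5 TPM), led by the transcription factor Mef2c at 129 ± 17.6 TPM (SD, n = 2). The stem cell factor Pax7, chosen after its values were seen, stood at 1.60 ± 0.198 TPM (SD, n = 2). Embryonic and neonatal muscle genes were detected in 11 of 16 cases (median 14.5 TPM). The sex chromosome list gave the pattern of male tissue: Ddx3y had 25.0 ± 1.39 TPM (SD, n = 2), while Xist, the RNA of the inactive X chromosome and also chosen after its values were seen, was listed at 0.010 TPM in both libraries.

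The 2 libraries were close in the level of most genes and differed in a limited set. Over 12156 genes with a mean of at least 1 TPM, the SD of the log2 difference was 0.30, and 134 genes differed over 2-fold, 63 higher in replicate 2 and 71 higher in replicate 1. The split was 41 against 79 in the second quantification and 22 against 82 with counts scaled by added RNA totals. Pearson's r was 0.986 and Spearman's rho 0.980 across genes, which are not independent replicates. Genes higher in replicate 1 included Fkbp5, a glucocorticoid-induced chaperone of steroid receptors (ENSMUSG00000024222.17, chromosome 17, 28399094 to 28517527), with 47.1 against 10.6 TPM. The metal-binding metallothioneins Mt2 (92.9 against 22.9 TPM) and Mt1 (58.1 against 15.8 TPM) and the secreted factor Angptl7 (32.5 against 7.52 TPM) were higher in the same library. Genes higher in replicate 2 included the stress-induced transcription factor Atf3 (ENSMUSG00000026628.13, chromosome 1, 191170296 to 191218039), with 1.88 TPM in replicate 1 and 15.6 TPM in replicate 2. Replicate 2 was also higher for the inducible heat shock proteins Hspa1a (1.71 and 8.29 TPM) and Hspa1b (1.19 and 6.06 TPM), the small GTPase Rrad (1.69 and 8.70 TPM) and the cytokine receptor Tnfrsf12a (8.43 and 23.7 TPM). The Z-disc protein Csrp3 (30.7 and 112 TPM), the actin-binding Xirp1 (21.6 and 58.6 TPM) and the adipocyte protease Cfd (1.62 and 10.3 TPM) were higher there too.

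Each of these named genes passed an exact binomial test on counts, with adjusted p-values from 2.3e-40 for Cfd downward. That test called 3610 of 17245 genes beyond sampling noise (20.9%), 1798 higher in replicate 2 and 1812 higher in replicate 1, so the libraries are not 1 library listed under both labels. The biological coefficient of variation estimated by edgeR was 0.119 over 14965 genes. The largest differences also held pseudogenes, little-studied genes and a small RNA: Gm24497, of the class snRNA (1175 against 24.9 TPM), Rpl7a-ps11 (20.9 TPM against a listed value of 0), Gm45837, 1700047I17Rik2, Gm20388 and Gm10163 in replicate 1, and Rps15a-ps7 and Gm14760 in replicate 2. For Gm24497 the authors' quantifier gave interval bounds of 19.3 to 1411 TPM in replicate 2, which overlap the bounds of 290 to 2195 TPM in replicate 1. The bounds of the 2 libraries also overlap for Rpl7a-ps11, Gm45837, 1700047I17Rik2, Gm20388, Gm10163 and Gm14760, so these differences are uncertain. Among these genes they lie apart only for Rps15a-ps7 (1.05 to 9.84 TPM in replicate 1 and 11.4 to 29.4 TPM in replicate 2). The binomial test covers counting error in these 2 libraries and compares no conditions. The number of genes over 2-fold apart was 226 with a pseudocount of 0.1, 55 above a mean of 5 TPM and 68 on counts scaled by TMM.

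**Figure D2:**
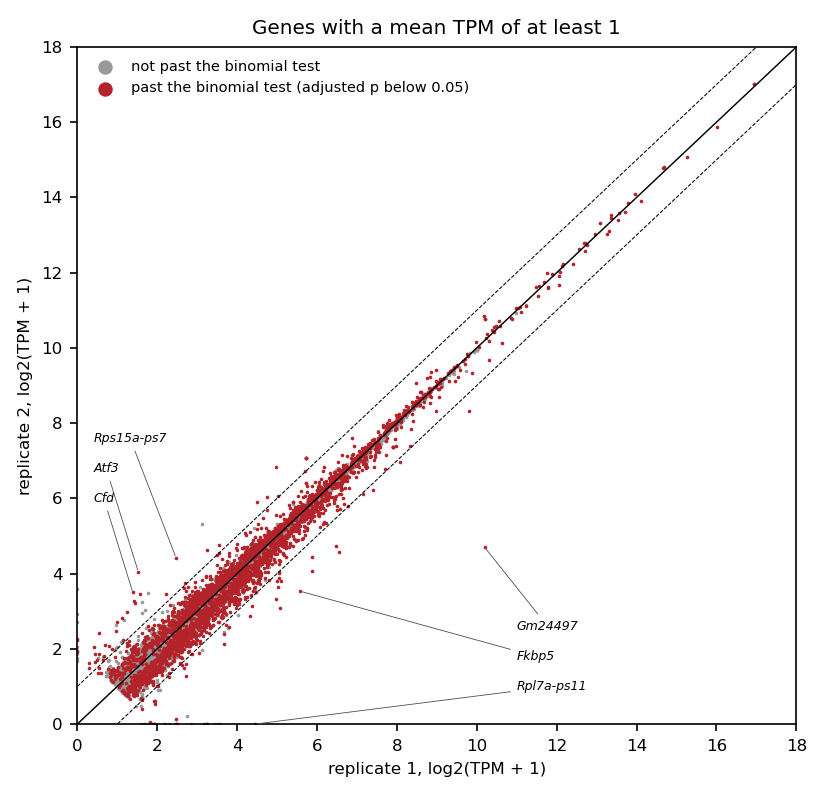
Each point is a gene with a mean of at least 1 TPM, placed by log2(TPM + 1) in replicate 1 (horizontal) and replicate 2 (vertical), in red where the exact binomial test passed. The solid line marks equal values and the dashed lines a 2-fold difference of TPM + 1, outside which 134 genes lie.

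Groups of genes also moved together between the libraries. Of 35 lists with enough detected members, 10 had a median difference below the 1st percentile of expression-matched random lists (lower in replicate 2). Another 4 had one above the 99th, against 0.7 lists outside for genes drawn at random. Genes of a list need not vary independently and some lists share members, so 0.7 is not a chance rate for such lists. Genes of fatty acid use and of muscle growth control were lower in replicate 2. All 15 fatty acid uptake and oxidation genes were higher in replicate 1, 14 of them past the binomial test, with a median log2 difference of -0.36, below all 10000 random lists. Pdk4, the kinase that turns the muscle from glucose to fat oxidation (ENSMUSG00000019577.6, chromosome 6, 5483351 to 5496309), had 893 TPM in replicate 1 and 317 TPM in replicate 2. The fatty acid carriers Cd36 (212 and 140 TPM) and Fabp3 (527 and 411 TPM) followed. Among atrophy and growth control genes 8 of 12 passed as higher in replicate 1 and 2 as higher in replicate 2, with a median of -0.64, also below all random lists. These included the ubiquitin ligase Trim63 (101 and 56.5 TPM) and the growth inhibitor Ddit4 (31.9 and 13.7 TPM). The ubiquitin ligase Fbxo32 (21.2 and 10.5 TPM) and the transcription factor Foxo1 (14.8 and 7.53 TPM), chosen after their values were seen, were higher in replicate 1 as well.

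Tendon, matrix, endothelial and cell division genes had lower relative levels in replicate 2, while fibro-adipogenic progenitor markers (percentile 23.1) and pericyte and smooth muscle markers (percentile 39.1) did not stand apart. Tendon markers had a median of -0.57, below all random lists, and 9 of 10 passed as higher in replicate 1 and 1 as higher in replicate 2, led by Fmod (88.9 and 55.0 TPM) and Thbs4 (64.9 and 45.5 TPM). The collagen and matrix group had a median of -0.15 (percentile 0.020), with 12 of 18 genes passing as higher in replicate 1 and 2 as higher in replicate 2. Col1a1 had 1597 and 1118 TPM. Endothelial markers had a median of -0.20 (percentile 0.240), with 7 of 12 passing as higher in replicate 1 and 1 as higher in replicate 2. In TPM all 12 were higher in replicate 1, and the 1 call for replicate 2 rests on the TMM-scaled counts of the binomial test. Cell division genes had a median of -0.33 (percentile 0.030), with 7 of 14 passing as higher in replicate 1 and none in the other direction, among them Top2a, Mki67 and Cdk1. Replication-dependent histone genes had a median of -0.26 (percentile 0.050), with 6 of 10 passing as higher in replicate 1 and 1 as higher in replicate 2. The long noncoding RNA list had a median of -0.21 (percentile 0.115), and 9 of 11 genes passed, all higher in replicate 1. Its most abundant member is the short RNA Rn7sk, so the list does not describe long noncoding RNAs alone. Mitochondrially encoded protein genes had a median of -0.14 (percentile 0.075), with 10 of 13 passing as higher in replicate 1 and 1 as higher in replicate 2. The only one with a higher TPM in replicate 2 was mt-Co3 (1152 and 1833 TPM). Taken with its identical nuclear copy, mt-Co3 was lower in replicate 2 (10963 and 10181 TPM), so its opposite direction depends on how reads were divided. Embryonic and neonatal genes had a median of -0.16 (percentile 0.705), and stood at percentile 4 in the second quantification.

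Red blood cell and nerve sheath genes had higher relative levels in replicate 2, while fast fibre and adipocyte genes gave less uniform results. Erythroid markers had a median of 0.43 (percentile 100), with 5 of 7 passing, all higher in replicate 2, including Hbb-bs (506 and 682 TPM) and Hba-a1 (462 and 654 TPM). Schwann cell markers had a median of 0.18 (percentile 99.8), with 6 of 10 passing, all higher in replicate 2, including the myelin gene Mbp (20.9 and 30.3 TPM). Adipocyte markers split: the median was 1.19 (percentile 100), with 4 of 7 passing as higher in replicate 2 and 3 as higher in replicate 1. That median is the value of a single low gene, Cidec (0.230 and 1.80 TPM; chosen after its values were seen), and it was 2.17 with a pseudocount of 0.1 and 0.83 with members down to 0.1 TPM. Plin4, a lipid droplet coat gene that muscle also expresses, had 140 and 67.9 TPM. Fast fibre genes had a median of 0.08 (percentile 99.2) on the TPM scale, but stood at percentile 97.9 in the second quantification and had a median of -0.16 when counts were scaled by added RNA totals. With counts scaled by added RNA totals the median difference of all genes was -0.25, against -0.04 on the TPM scale, so the differences above are relative to the other genes of a library. The other 21 lists lay between the 1st and 99th percentile, with medians from -0.22 to 0.05.

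**Figure D3:**
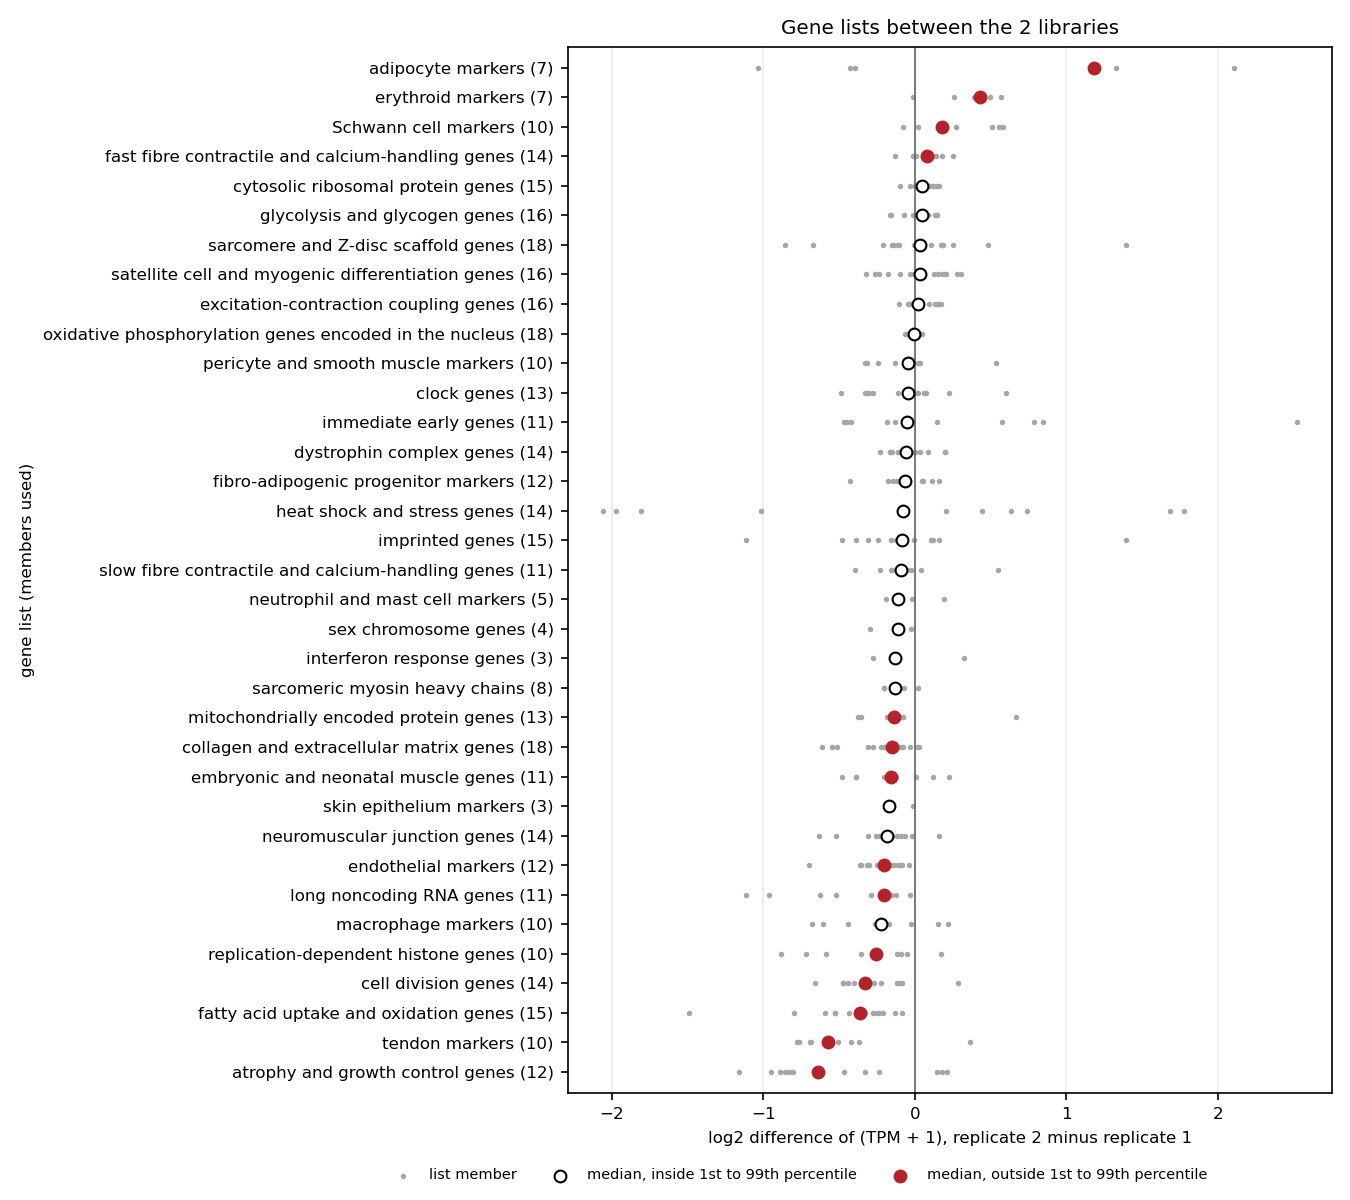
Each row is a gene list with the number of members used; grey points are its members and the large circle is their median, on a horizontal axis of the log2 difference of (TPM + 1), replicate 2 minus replicate 1. Filled red circles are the 14 lists outside the 1st to 99th percentile of random lists, from -0.64 for atrophy and growth control genes to 1.19 for adipocyte markers.

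Of 30 genes chosen for known alternative splicing, 15 had a transcript with at least 50% of the gene's TPM. The tropomyosin transcript Tpm1-205 (ENSMUST00000113685.9, chromosome 9, 67027892 to 67049213, 10 exons) took 97.3 ± 0.0339% of Tpm1, and Atp2a1-201 (ENSMUST00000032974.12, chromosome 7, 126445858 to 126463108, 23 exons) took 95.6 ± 0.244% of the calcium pump (SD, n = 2 for both). Ryr1-202, of the calcium release channel, took 93.7 ± 1.71%, Tpm3-205 took 86.0 ± 2.46%, and Ldb3-207, of a Z-disc protein, took 76.4 ± 1.01% (SD, n = 2 for each). Bin1-205, of the protein that shapes the T-tubules, took 71.7 ± 0.944% (SD, n = 2). Dystrophin was led by Dmd-203, a transcript of 79 exons, with 63.0 ± 2.49% (SD, n = 2). The pyruvate kinase gene Pkm was divided between Pkm-202 (53.3 ± 0.815%) and Pkm-201 (44.9 ± 0.545%; SD, n = 2 for both). The same transcript led in both libraries for 28 of the 30 genes, with a median SD of 0.711 percentage points. In the second quantification the leading transcript was another one for 7 genes (Pkm, Tnnt3, Tnnt1, Ttn, Mbnl1, Myl1 and Capzb), and shares differed by a median of 10.9 percentage points. For Myl1, Myl1-202 took 67.0 ± 0.750% in the transcript table from aligned reads and 27.0 ± 0.548% in the second quantification (SD, n = 2 for both). Tpm1-205 took 75.4% in the second quantification, Tpm3-205 69.2%, Bin1-205 56.4% and Dmd-203 56.6%. Shares closer to those above were 97.5% for Atp2a1-201, 89.3% for Ryr1-202 and 73.6% for Ldb3-207. A small SD between the libraries therefore does not cover the uncertainty of a share.

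The 2 quantifications of the same reads differed over 2-fold for 8.33% of genes in replicate 1 and 8.42% in replicate 2. Rn7sk had a mean of 16520 TPM in the gene table and 0.489 TPM in the second quantification, and the mitochondrial gene mt-Atp8 had 3770 TPM against a listed value of 0. Cycs, encoding cytochrome c, had 52.0 TPM against 716 TPM; mt-Atp8 and Cycs were chosen after their values were seen. Gapdh had 4579 TPM against 12762 TPM, and Acta1 had 27605 TPM against 56647 TPM. Genes over 2-fold apart numbered 1061 of 12740 in replicate 1 and 1052 of 12489 in replicate 2. Pearson's r across genes was 0.850 in both libraries, and Spearman's rho was 0.884 and 0.882. Genes are not independent replicates, so no p-value is given.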

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

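Of these alternatives, the scaling of the list differences by TMM, size factors and added RNA totals was chosen after seeing the data. All 14 fast over slow pairs kept their direction and their side of the threshold with a pseudocount of 0.1, a filter at 5 TPM and the second quantification, and 14 were over 2-fold in both libraries. Of the 26 mature over developmental or ubiquitous pairs, only Cox7a1 over Cox7a2 turned, to -0.19 (adjusted p = 0.123, limma) in the second quantification, and the cause was not tested. Without either library 14 and 26 pairs kept their direction, the Myh4 share was 78.9% to 80.4%, the share of the 10 highest genes 47.3% to 47.8%, and 15 to 16 genes had a transcript with at least 50% of TPM. In the second quantification the Myh4 share was 73.6%, against 80.6% as a share of counts, and the cause was not tested. The 10 highest genes took 36.6% in the second quantification, in which abundant short RNAs such as Rn7sk are low, and 30.9% among nuclear protein-coding genes, where those RNAs are left out. The number of genes over 2-fold apart was 55 above 5 TPM, where fewer genes are tested. Their share also fell there, from 1.10% to 0.734%. Of the 134 genes in the main setting, 79 lay from 1 to 5 TPM, where the SD was 0.344, against 0.271 from 5 to 20 TPM. The number was 226 with a pseudocount of 0.1, which shrinks ratios less, 68 with TMM and 68 with size factors. The TMM and size factor settings also replaced TPM by CPM, which is not corrected for gene length. The TMM factors were 1.006 and 0.994, so the fall goes with the unit more than with the scaling. How the unit acts was not tested. Without a count filter the coefficient of variation was 0.126, with more genes of low count. Quantifications differed over 2-fold at 682.5 genes per library above 5 TPM, where fewer genes are tested, against 1056.5. Genes beyond sampling noise numbered 3323 to 3634 over the alternatives run.

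Between 12 and 15 lists stood outside the 1st to 99th percentile, against 14. The fast fibre list reversed to -0.16 when scaled by added RNA totals, under which the median of all genes was -0.25, and stood at percentile 97.9 in the second quantification. The immediate early list reversed to 0.12 (percentile 99.6) with members down to 0.1 TPM, which adds 3 genes of low level. The embryonic list stood at percentiles 1.22 and 4 and the synapse list at 0.8, 0.880 and, in the second quantification, 8.81 under single alternatives, and the cause was not tested. Genes below the floor of 0.0740 to 0.0811 CPM cannot be told from absent ones.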

Other observations

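Of the tests reported in this part, that of a different share of slow fibres and that of nuclear copies of mt-Co2 were chosen after the result was seen. Several gene groups that the comparisons leave out describe the state of the muscle at 14 days. Imprinted genes reached 1 TPM in both libraries in 14 of 17 cases (median 30.2 TPM). H19 and Igf2 were followed by Gnas, a G protein subunit gene (731 ± 25.4 TPM), and Cdkn1c, a cell cycle inhibitor (249 ± 8.32 TPM; SD, n = 2 for both). Synapse genes were detected in 14 of 15 cases (median 9.30 TPM), with the receptor subunit Chrnb1 at 31.2 ± 4.06 TPM and acetylcholinesterase (Ache) at 21.5 ± 0.693 TPM (SD, n = 2 for both). Of 14 synapse genes used, 5 passed the binomial test, all higher in replicate 1, and the list median of -0.19 stood at percentile 1.15. Interferon response genes were low, with 3 of 12 reaching 1 TPM in both libraries (median 0.320 TPM).

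Clock genes were detected in 12 of 14 cases (median 7.96 TPM), and the list median did not stand apart (percentile 53.0). Single members differed: Per1 had 35.0 TPM in replicate 1 and 28.2 TPM in replicate 2, while Nr1d1, a repressor that works against the activating arm of the clock, had 12.3 and 19.3 TPM. Immediate early genes were detected in 11 of 14 cases (median 4.53 TPM) and went both ways, with 4 of 11 passing in each direction. Nr4a1 had 22.1 and 38.9 TPM, and the phosphatase gene Dusp1 had 35.1 and 25.2 TPM. Heat shock and stress genes also split (14 of 14 detected, median 26.2 TPM). Of these, 7 passed as higher in replicate 2, including the chaperones Hspa8 (428 and 582 TPM) and Hspb1 (116 and 194 TPM), and 4 passed as higher in replicate 1, the metallothioneins among them. Sarcomeric myosins were detected in 8 of 9 cases (median 171 TPM) with a list median of -0.13 at percentile 1.99. The long noncoding RNA list, which also holds short RNAs such as Rn7sk, had 11 of 14 members detected (median 135 TPM). Sex chromosome genes were detected in 4 of 7 cases (median 3.98 TPM).

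The fatty acid and the growth control lists together were lower in replicate 2, with 24 of 27 members higher in replicate 1 and a median of -0.36 (1.28-fold). GC content or transcript length bias is argued against, since among random lists matched on expression, GC content and length, whose median was -0.03, the lists stood at percentile 0. A different share of slow fibres was not settled. The median of the lists minus that of the slow fibre list (-0.09) was -0.27, so the slow fibre list fell less. The bootstrap 95% interval was from -0.50 to -0.13, but it treats genes as independent. This comparison cannot decide the question, since the lists were taken up for their low medians, which were known beforehand. The slow fibre list also holds Mybpc1, which fast fibres make too. A glucocorticoid and FOXO response is a candidate. A separate list of 22 of its target genes, none of them in another list, also stood at percentile 0. All 22 were higher in replicate 1 (median 1.44-fold), for example Glul (168 and 73.0 TPM), Txnip (207 and 109 TPM) and Angptl4 (11.7 and 3.36 TPM). The explanation was raised by the pattern in these same 2 libraries, though its list was written before its values were viewed. Random lists are drawn without regard to shared regulation, so the result cannot single out this cause. The labels give no feeding state, time of day or handling, so what separates the libraries stays open and no biological explanation tied to the design was tested.

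The mitochondrial gene mt-Co2, encoding a cytochrome oxidase subunit, was listed at 87.8 ± 6.98 TPM (SD, n = 2), while the other 12 mitochondrial protein genes lay between 629 and 11353 TPM. Reads shared with nuclear pseudogene copies are a candidate explanation: Gm28661 (chromosome 1, 24614885 to 24615565) is identical to mt-Co2 over 681 bases, 99.6% of the gene, and mt-Co2 with this copy reached 13060 ± 638 TPM (SD, n = 2). That sum lies above the highest other gene as listed and below mt-Co1 taken with its own partial copy (16059 TPM). Comparing sums with copies on both sides was settled after the value was seen. The copy of mt-Co1 covers only 31.3% of that gene, and TPM is scaled by length, so its sum is not a true total. Whether mt-Co2 with its copy lies within the range of the other genes is therefore not settled. In the second quantification mt-Co2 had 941 ± 61.5 TPM alone and 19407 ± 692 TPM with the copy (SD, n = 2 for both). Copies in the same region were also near-identical to mt-Co3 and mt-Atp6 (100% identity each) and held TPM of their own, so single values of these genes stay uncertain, and no biological explanation was tested.

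Some adipocyte genes at low levels were higher in replicate 2, namely Cfd and, chosen after their values were seen, Adipoq (0.420 and 2.24 TPM) and Plin1 (0.220 and 2.07 TPM), while Plin4, Pnpla2 and Fabp4 of the same list were lower. Adipose tissue carried over with the muscle might be the source, but a separate list of 13 adipocyte genes did not settle it. The 11 of them at or above 0.1 TPM, 8 of which reached a mean of 1 TPM, had a median of 0.09 at percentile 97.1, short of the 99th, with 6 higher in replicate 2. Scd1 (5.77 and 11.5 TPM) and Pck1 (0.370 and 2.61 TPM) were higher in replicate 2, and Lipe (8.48 and 6.07 TPM) and Dgat2 (17.1 and 12.5 TPM) were lower. Fabp4 (171 and 130 TPM) is also expressed in vessels, so a small carry-over and a change in other cells cannot be told apart at these low levels.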
